A study of Mus musculus with 2 samples.

How the data were processed

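Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in hindbrain dissected from mouse embryos at 11.5 days of development. There were 2 libraries in 1 group. Per the labels they are biological replicates 1 and 2, made from 109 and 88 pooled embryos, and they are called library 1 and library 2 here. No other condition was sampled, so there was no comparison between groups of samples, and no paired analysis was possible because the design holds a single group.

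The deposited files are 12 lists of peaks on the mouse genome build mm10. Per the deposited provenance notes, each library's lists were derived from the alignments of that library, and the lists of the whole series from the alignments of both libraries. For each library and for the pair, the authors deposited peaks ranked by irreproducible discovery rate (IDR, a measure of how well ranks repeat between replicates), IDR-thresholded peaks and pseudoreplicated peaks. For the pair they also deposited a conservative IDR-thresholded list and a replicated list. The aligner, the peak caller and their versions are not given in the sources used here. The score in the deposited lists is the integer display score of the bed format, and it was used only to set the ranked lists beside the thresholded ones. The signal value in the deposited lists is the narrowPeak signal of each peak as the authors' caller gave it, and it was used only to describe, rank or filter peaks within a list. The deposited lists also hold the minus log10 p-value of each peak or, in the ranked lists, the minus log10 IDR, and neither was used. No file holds read counts, so the sequencing depth of the libraries is unknown and no interval that needs it is given.

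Each line of a deposited list is a summit, and several summits can share an interval. The unit here is the distinct region, represented by its summit with the highest signal. This unit was chosen after the lists had been examined, and counting every summit was tried as an alternative. The main set was the conservative IDR-thresholded list, and the IDR-thresholded list of each library was analysed beside it. The other choices of unit, window, gene list, motif and test, and the rule for named genes, were fixed before the data were examined.

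Regions of the 2 libraries were called shared when they overlapped by 1 bp or more. The shares carry Wilson intervals at the 95% level over regions, which are not replicates. Library 2 was moved to random places on the same chromosomes in 100 shuffles. Spearman's rho and Pearson's r of log2 signal across shared regions are descriptions, since regions are not independent replicates. The reference was the GRCm38 sequence with the GENCODE M21 annotation. A region was assigned to a promoter when its summit lay within 1000 bp of an annotated transcription start site (TSS) of any gene, and otherwise to an exon, an intron or intergenic sequence. The promoter of a protein-coding gene was called open when a region overlapped the 1000 bp either side of one of its TSSs. A distal region had its summit over 1000 bp from every TSS and was given to the protein-coding gene of the nearest TSS within 100 kb.

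The tests used 20 gene lists: Hox paralog groups 1 to 4, 5 to 8 and 9 to 13, isthmus and rhombomere patterning genes other than Hox, dorsal hindbrain, ventral hindbrain, neural progenitors, neurons, forebrain, midbrain, neural crest and glia, mesenchyme, endothelium, erythroid cells, macrophages and microglia, surface epithelium, hepatocytes, muscle, gut and pancreas, and housekeeping genes. Open promoters of a list were compared with those of all other protein-coding genes by a two-sided Fisher's exact test. Mean distal regions per gene were compared with 10000 random lists of the same size, matched in 20 bins on the territory nearest to each gene's TSSs, and the smallest two-sided p they can give is 0.0002. Hox paralog groups 1 to 4 were compared with groups 9 to 13 in regions per kb of gene body with 1 kb either side, by a two-sided permutation test over genes with 100000 permutations. For each of 30 consensus motifs, matches on either strand were sought in the 200 bp centred on each summit. They were compared with those in the 2 flanking windows of 200 bp that start 400 bp away. These windows were not required to lie outside the region. Shares and ratios use both flanks. The test was an exact binomial test of McNemar type against a single flank drawn at random for each region. The p-values were adjusted by Benjamini-Hochberg over the 20 lists or the 30 motifs, and an adjusted p under 0.05 is a call. These p-values are over genes or regions, which are not replicates of the tissue, and neighbouring genes share regions.

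The named genes are the 2 members of each list with the most distal regions in the conservative list (ties by the strongest region), every Hox gene, the 20 protein-coding genes with the most distal regions, the 10 strongest regions with the gene of the nearest TSS, and for each library the 5 strongest regions with no overlap in the other library's pseudoreplicated list. The methods were tested on simulated data. Of lists simulated with a 3-fold rate of distal regions 92.0% were called, against 2.0% of unchanged lists. Of lists simulated with 95.0% open promoters 100% were called, against 0% of unchanged lists. All planted motifs and 3.70% of the others were called in 5000 windows. The simulated summits and flanks had the same base composition. The rate of 3.70% therefore does not show how a difference in composition affects the motif test. The Hox test called 3.50% of draws with shuffled values, and a simulated overlap of 69.4% was recovered as 69.7%. Shuffling removes the dependence between neighbouring Hox genes, so the rate of 3.50% does not show how that dependence affects the test.

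The alternatives were other deposited lists, the 50% of regions with the highest signal, a promoter window of 500 or 2500 bp, a reach of 50 or 250 kb, random lists without matching on territory, motif windows of 100 or 400 bp, dinucleotide-shuffled controls, other definitions of overlap, and each library alone. With 2 libraries, leaving out a replicate leaves the list of the other library. Counting every summit, and reducing library 1 to its 16912 strongest regions, were added after the data had been seen. Copies of regions elsewhere in the genome and matches to mitochondrial DNA were found with blastn 2.17.0. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.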

Results

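The deposited data are lists of accessible chromatin regions in the hindbrain of mouse embryos at 11.5 days, a stage at which the neural tube behind the midbrain holds dividing progenitors and newly formed neurons. ATAC-seq was run on 2 biological replicates, library 1 from 109 pooled embryos and library 2 from 88. The series compares no conditions, and its comparisons are those between the libraries, between gene lists and between parts of the genome. The read depth is unknown because the files hold no counts. All positions are on mm10, and signal is the authors' value for a region, which has no replicate error of its own.

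Both libraries marked largely the same regions, with library 1 giving the longer list. Library 1 had 22148 regions that covered 23.8 Mb, and library 2 had 16912 that covered 17.1 Mb, a mean of 19530 ± 3702 (SD, n = 2). The ratio of library 1 to library 2 was 1.31. Of the library 2 regions, 16082 (95.1%, Wilson 95% interval 94.8% to 95.4%) overlapped a library 1 region. Of the library 1 regions, 15885 (71.7%, 71.1% to 72.3%) overlapped a library 2 region. Randomly placed library 2 regions overlapped library 1 in 1.81% ± 0.10 of cases (SD over 100 shuffles). Most regions found in a single thresholded list were in the other library's longer pseudoreplicated list, from which 664 library 1 regions and 40 library 2 regions were absent.

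The signal of shared regions ranked alike in both libraries. Across the 15885 library 1 regions that overlap a library 2 region, Spearman's rho was 0.909 and Pearson's r of log2 signal was 0.907. The mean log2 ratio of library 1 to library 2 was 0.07 with an SD of 0.22 over regions, and the median distance between summits was 14 bp. Among distal regions alone rho was 0.786, and among promoter regions alone it was 0.920.

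**Figure D1:**
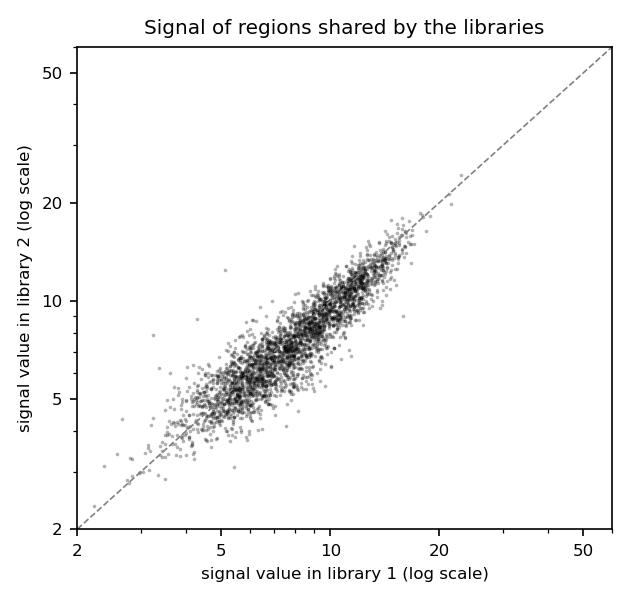
Signal of shared regions in library 1 (horizontal axis) and library 2 (vertical axis), both the authors' signal value on log axes, with a random 3000 of the 15885 shared regions as points and the line of equality. The points follow the line, with rho 0.909 over all shared regions.

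The conservative list, called on both libraries, was most concentrated at promoters. It held 25328 regions over 27.7 Mb, or 1.01% of the genome, with a median width of 1091 bp. Summits within 1000 bp of a TSS made up 53.7% of these regions (13592), against 5.88% of the genome, a 9.13-fold excess. Introns held 21.4% of the summits against 37.3% of the genome, intergenic sequence 22.6% against 53.7%, and exons 2.43% against 3.09%. The promoter share was 58.6% in library 1 and 67.8% in library 2 (63.2% ± 6.49, SD, n = 2), and in the longer replicated list, which reaches weaker regions, it was 30.5%. Regions at promoters had a median signal of 7.88 and a median width of 1260 bp, and the 11736 distal regions had medians of 4.98 and 852 bp.

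Nearly all promoters of the neural progenitor, neuronal and housekeeping lists were open, and few of those of several non-neural lists were. In the conservative list 12828 of 21938 protein-coding genes (58.5%) had an open promoter, as did 12485 in library 1 (56.9%) and 11340 in library 2 (51.7%). All 22 neural progenitor genes had an open promoter, among them Sox2, Nes, Hes5 and Pax6 (adjusted p 0.000187). Of the 25 genes of postmitotic neurons 24 did, with Nhlh2 the exception (adjusted p 0.00022), and all 20 housekeeping genes did (adjusted p 0.000207). These 3 lists were called in each library too. Among the 50% of conservative regions with the highest signal only the housekeeping list was still called higher. The same held when library 1 was reduced to the length of library 2, where the adjusted p was 0.325 for progenitor and 0.0659 for neuronal genes.

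The lists with fewer open promoters than other genes were those of tissues outside the nervous system and of the more posterior Hox genes. Open promoters were found at 1 of 14 surface epithelium genes and 2 of 17 hepatocyte genes (adjusted p 0.000317 for each). They were found at 2 of 19 muscle genes (adjusted p 0.000204), 3 of 16 macrophage and microglia genes (0.00402), 4 of 17 erythroid genes (0.0115) and 4 of 16 gut and pancreas genes (0.0186). Hox paralog groups 5 to 8 had 2 of 11 open (0.0194) and groups 9 to 13 had 3 of 16 (0.00402). In the longer replicated list the calls for surface epithelium (adjusted p 0.0547), gut and pancreas (0.263) and both Hox groups (0.758 for groups 5 to 8 and 0.171 for groups 9 to 13) were absent. The call for groups 5 to 8 was absent in the optimal list (0.533) and in library 1, where 4 of 11 were open and the adjusted p was 0.281. Endothelial genes, at 6 of 17, were not called in the conservative list (0.117) but were lower in library 2 alone, at 2 of 17 (0.00176).

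The regional lists of the brain were not called in the conservative list. The isthmus and rhombomere list, which holds genes of the midbrain-hindbrain organiser and of segment identity such as En1, Gbx2, Fgf8 and Egr2, had 20 of 25 promoters open (adjusted p 0.0668). It had the same count in library 1, where it passed (0.0446), and 18 in library 2 (0.0659). The promoters of Fgf8, Fgf17, Wnt1, Cyp26b1 and Cyp26c1 were not open in the conservative list or in either library. Those of En1 and Gbx2 were open in library 1 and not in library 2. Dorsal hindbrain genes had 17 of 22 open and ventral hindbrain genes 9 of 23 (adjusted p 0.117 for each). The forebrain list had 12 of 23 open (0.668) and the midbrain list 7 of 11. In library 1 and library 2 the counts were 8 and 7 for forebrain, and 5 and 2 for midbrain genes. Both lists lay below other genes in each library without a call. For midbrain genes in library 2 the shares were 18.2% against 51.7% (adjusted p 0.0511). The calls of the regional lists depended on the list of regions. Among the 50% of highest signal, dorsal hindbrain (-31.6 points against other genes, adjusted p 0.00516), ventral hindbrain (-27.9 points, 0.0185) and forebrain genes (-27.9 points, 0.0185) were called lower. Ventral hindbrain (0.0109) and forebrain genes (0.0304) were also lower in library 1 reduced to the length of library 2, and dorsal hindbrain genes were higher in the replicated list (0.0387). Neural crest and glia (7 of 11), mesenchyme (10 of 18) and Hox groups 1 to 4 (8 of 12) were not called either. Mesenchyme genes were called lower among the 50% of highest signal (-28.6 points, adjusted p 0.0254). Hox groups 1 to 4 lay above other genes in the conservative list (66.7% against 58.5%) and below them in library 1 (41.7% against 56.9%) and library 2 (25% against 51.7%), and were called lower in the reduced library 1 (-35.0 points, adjusted p 0.0304).

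**Figure D2:**
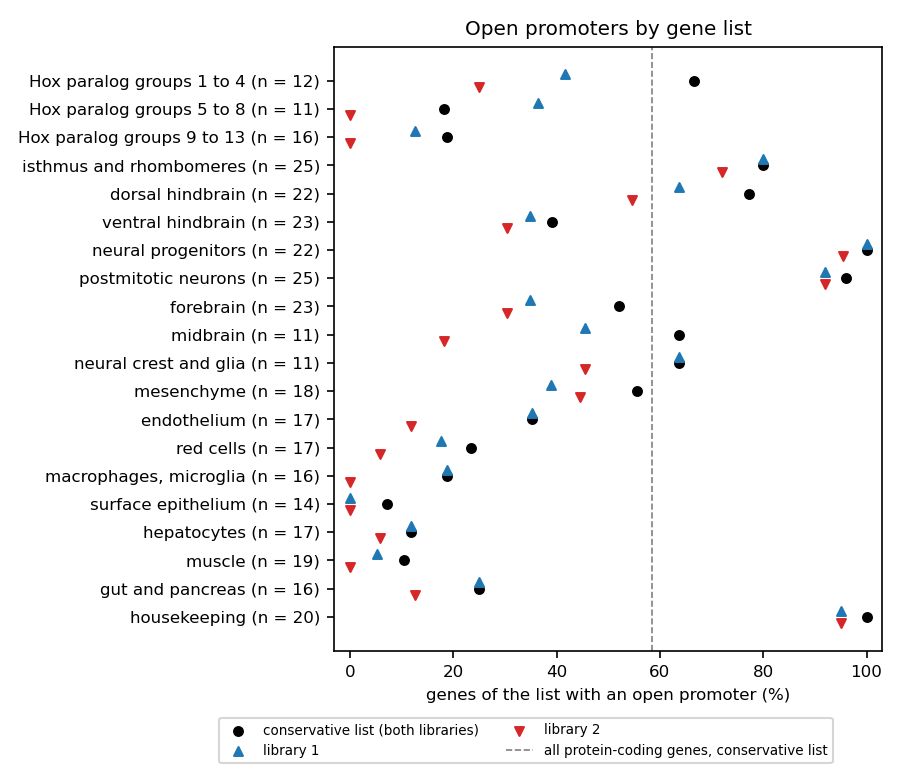
Percent of the genes of each list with an open promoter, on a horizontal axis from 0 to 100%, in the conservative list and in each library, with the share of all protein-coding genes as a line. Neural progenitor and housekeeping genes reach 100% in the conservative list, and the surface epithelium, muscle and hepatocyte lists lie lowest.

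Distal regions gathered around genes of hindbrain patterning, neural progenitors and neurons. Of the 11736 distal regions in the conservative list, 8729 (74.4%) had a protein-coding TSS within 100 kb. Neural progenitor genes had a mean of 2.73 distal regions, 4.72-fold the mean of 0.578 in random lists of matched territory. Dorsal hindbrain genes had 2.14 against 0.548 (3.90-fold), isthmus and rhombomere genes 2.36 against 0.889 (2.65-fold), and neuronal genes 2.36 against 0.958 (2.46-fold). Each of these 4 lists had an adjusted p of 0.002, and their calls held in both libraries. In library 1 and library 2 the means were 2.55 and 1.77 for progenitor, 1.95 and 1.05 for dorsal hindbrain, 1.56 and 1.36 for isthmus and rhombomere, and 2.2 and 1.44 for neuronal genes. Ventral hindbrain genes had 1.13 against 0.513 (2.2-fold, adjusted p 0.0392). That call was absent in each library, where the means were 0.87 (adjusted p 0.0992) and 0.565 (adjusted p 0.17). Among the 50% of regions with the highest signal the dorsal hindbrain (adjusted p 0.118) and neuronal (0.0547) calls were absent, and in library 1 reduced to the length of library 2 the isthmus and rhombomere call was (0.0530).

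At least 1 distal region was present at 19 of the 22 dorsal hindbrain genes, 21 of the 25 isthmus and rhombomere genes, 18 of the 22 progenitor genes and 22 of the 25 neuronal genes. Meis2 and Pbx1, homeodomain cofactors of Hox proteins, had 8 and 7 distal regions. Pax3 and Olig3, which mark dorsal progenitors, had 8 and 6. Notch1 and the proneural gene Ascl1 had 7 and 6, and Myt1l and Ebf1, transcription factors of newly formed neurons, had 6 each. Foxa2 of the floor plate had 3 distal regions although no region was called at its promoter, and Gata3 had 2. In library 1 and library 2 the counts were 6 and 6 for Meis2, 4 and 4 for Pbx1, 6 and 5 for Pax3, 6 and 4 for Olig3, 5 and 4 for Notch1, 4 and 4 for Ascl1, 7 and 4 for Myt1l, 7 and 3 for Ebf1, 2 and 2 for Foxa2 and 1 and 1 for Gata3.

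The strongest distal region of Olig3 lay at chromosome 10, 19309613 to 19310523, 46326 bp from its TSS in another gene's intron (signal 11.4). That of Ascl1 lay at chromosome 10, 87447003 to 87448468, in intergenic sequence 45803 bp away, with a signal of 11.3. For Myt1l it lay in an intron at chromosome 12, 29871903 to 29872956 (signal 10.3). For Meis2 it lay at chromosome 2, 116103379 to 116103900 (signal 6.85), with the 41 bp at the summit reading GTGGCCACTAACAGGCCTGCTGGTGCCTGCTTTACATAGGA, which holds the ZIC consensus CCTGCTGG. For Ebf1 it lay at chromosome 11, 44892811 to 44893531 (signal 7.19), with the sequence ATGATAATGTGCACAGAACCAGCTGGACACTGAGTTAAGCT and the E-box CAGCTG. All 5 of these regions were present in both libraries.

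No list had fewer distal regions than random lists past the threshold, in the conservative list or in either library. A lower call was not possible where the 2.5 percentile of the random lists was 0. In the conservative list this held for all Hox lists, the erythroid list and the housekeeping list. It held for further lists in each library. Forebrain genes had a mean of 0.87 against 0.475 (adjusted p 0.257) and midbrain genes 1.18 against 0.573 (0.257). In the longer replicated list both were called higher, with an adjusted p of 0.0020 for forebrain and 0.0257 for midbrain. Fezf1, Otx1, Otx2 and Dmbx1, which are genes of forebrain or midbrain identity, had 3 distal regions each, and no region was called at the promoter of Otx2. In library 1 and library 2 the counts were 3 and 1 for Fezf1, 1 and 1 for Otx1, 4 and 1 for Otx2 and 2 and 2 for Dmbx1. Housekeeping genes had 0.4 against 0.177 (0.329), neural crest and glia 0.818 against 0.496 (0.616), gut and pancreas 0.812 against 0.496 (0.501), and macrophages and microglia 0.688 against 0.465 (0.703). Below the random mean were mesenchyme at 0.556 against 0.728, endothelium at 0.412 against 0.619, surface epithelium at 0.357 against 0.515, hepatocytes at 0.235 against 0.294 and erythroid cells at 0.118 against 0.147, while muscle was at 0.316 against 0.307. Some of these uncalled directions turned in a single library. In library 2 endothelium (0.294 against 0.289), hepatocytes (0.176 against 0.135) and erythroid cells (0.118 against 0.0721) lay above the random mean. Macrophages and microglia lay below it in library 2 (0.188 against 0.216), and muscle in library 1 (0.211 against 0.240). Hox groups 1 to 4 had 0.25 against 0.147. All 3 of their regions lay at Hoxc4, and none was in the thresholded list of library 2. These groups were called higher in the replicated list (adjusted p 0.0365). Groups 5 to 8 had 0 against 0.0415 and groups 9 to 13 had 0.0625 against 0.113.

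Some genes of lists that were not called had distal regions, counted here at any signal. The strongest of each gene named here lay above the distal median signal of 4.98, except at Col1a2 and Grhl2. Ednrb, the endothelin receptor of migrating neural crest, had 4 in the conservative list and in each library, the strongest at chromosome 14, 103898622 to 103899863, with a signal of 11.2. Ptprc and Lgr5 had 4 each, Foxd3, Foxc1, Col1a2, Sox17, Cdh5, Spi1, Grhl2, Apob, Hand2 and Myh3 had 2 each, and Klf1, Tal1, Krt8 and Apoa1 had 1 each. In library 1 and library 2 the counts were 2 and 2 for Ptprc, 5 and 3 for Lgr5, 2 and 0 for Spi1, 1 and 0 for Col1a2, 1 and 2 for Apob and 0 and 0 for Apoa1. They were 2 and 1 for Foxd3 and Myh3, 1 and 1 for Foxc1 and Grhl2, and unchanged for Sox17, Cdh5, Hand2, Klf1, Tal1 and Krt8. The strongest distal region had a signal of 10.4 at Sox17, 9.16 at Krt8 and 9.14 at Ptprc, each present in both libraries. It had a signal of 4.22 at Col1a2, 4.60 at Grhl2 and 5.29 at Apoa1, each without an overlap in the IDR-thresholded list of either library. Overlap with the longer pseudoreplicated lists was not examined for them. Of the housekeeping genes, Ywhaz had 3 and Eef1a1 had 2. The strongest distal region lay little past the promoter limit of 1000 bp at Klf1 (1288 bp), Grhl2 (1355 bp) and Apoa1 (1381 bp). The assignment is by distance alone.

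**Figure D3:**
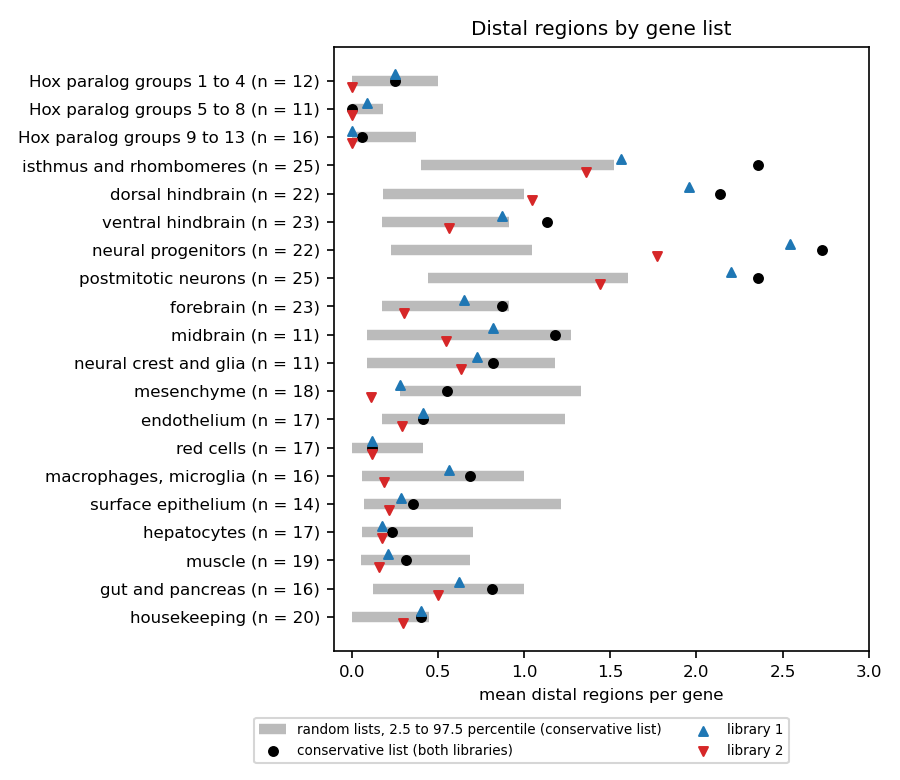
Mean number of distal regions per gene for each gene list (horizontal axis, regions per gene), in the conservative list and in each library, with the range of 95% of the matched random lists. Neural progenitor genes, at 2.73, isthmus and rhombomere genes, at 2.36, and neuronal genes, at 2.36, lie highest.

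Over all protein-coding genes, Celf4, an RNA-binding protein of neurons, had the most distal regions in the conservative list, 17, and led in neither library. It was followed by Gse1 with 16, the synaptic adhesion gene Nrxn3 and the transcription factor Bach2 with 15 each, and Frmd4a and Maml3 with 14 each. Robo1, an axon guidance receptor, Srgap3, which acts in the same pathway, and Sfi1 had 13 each, Nav2 and Casz1 had 12 each and Bcor had 10. Sertad2, Tmem108, Ralgapa2, Tead1, Cacna2d1, Trim27, Foxn3 and Cdk14 had 9 each. These 20 genes had 4 to 15 distal regions each in library 1 and 3 to 10 in library 2. Library 2 had fewer than library 1 at Celf4 (5 against 12), Gse1 (7 against 15), Frmd4a (6 against 14) and Robo1 (4 against 12), and more at Sfi1 (7 against 4). For Sfi1, 8 of the 13 regions have near-identical copies elsewhere in the genome and their placement is uncertain, and 2 of the 9 regions of Foxn3 do. This ranking was not matched on territory or tested for shared functions, and the territories differ in length, with 831 kb for Nrxn3, 691 kb for Frmd4a and 420 kb for Celf4.

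Anterior Hox genes carried more accessible regions than posterior ones. Genes of paralog groups 1 to 4, which pattern the rhombomeres, had 0.148 ± 0.120 regions per kb (SD, n = 12 genes). Groups 9 to 13, which act in the lumbosacral cord, limb and tail, had 0.0324 ± 0.0734 (n = 16 genes), a difference of 0.116 (permutation p 0.00474). The means of groups 1 to 4 were 0.0809 in library 1 and 0.0499 in library 2. The difference was 0.0657 in library 1 (permutation p 0.0287) and 0.0499 in library 2 (permutation p 0.0150), where no gene of groups 9 to 13 had a region. Hox gene bodies overlap, so a region can count for more than 1 gene and the genes are not independent.

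Open promoters were found at Hoxa1, Hoxb1, Hoxd1, Hoxa2, Hoxb3, Hoxd3, Hoxa4 and Hoxb4, and no region was called at those of Hoxb2, Hoxa3, Hoxc4 and Hoxd4. In groups 5 to 8 only Hoxb5 and Hoxa7 were called open in the conservative list, and in groups 9 to 13 only Hoxd9, Hoxd10 and Hoxc13. The 8 of 12 open anterior promoters differed from the 3 of 16 posterior ones (Fisher's exact p 0.0189). In library 1 alone the counts were 5 and 2 (Fisher's exact p 0.103) and in library 2 alone 3 and 0 (Fisher's exact p 0.0672). Hoxa1 and Hoxd1 were open in both libraries, with signals of 6.97 and 7.09 in the conservative list. Hoxc13, with a signal of 7.09, was open in library 1 and not in library 2.

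**Figure D4:**
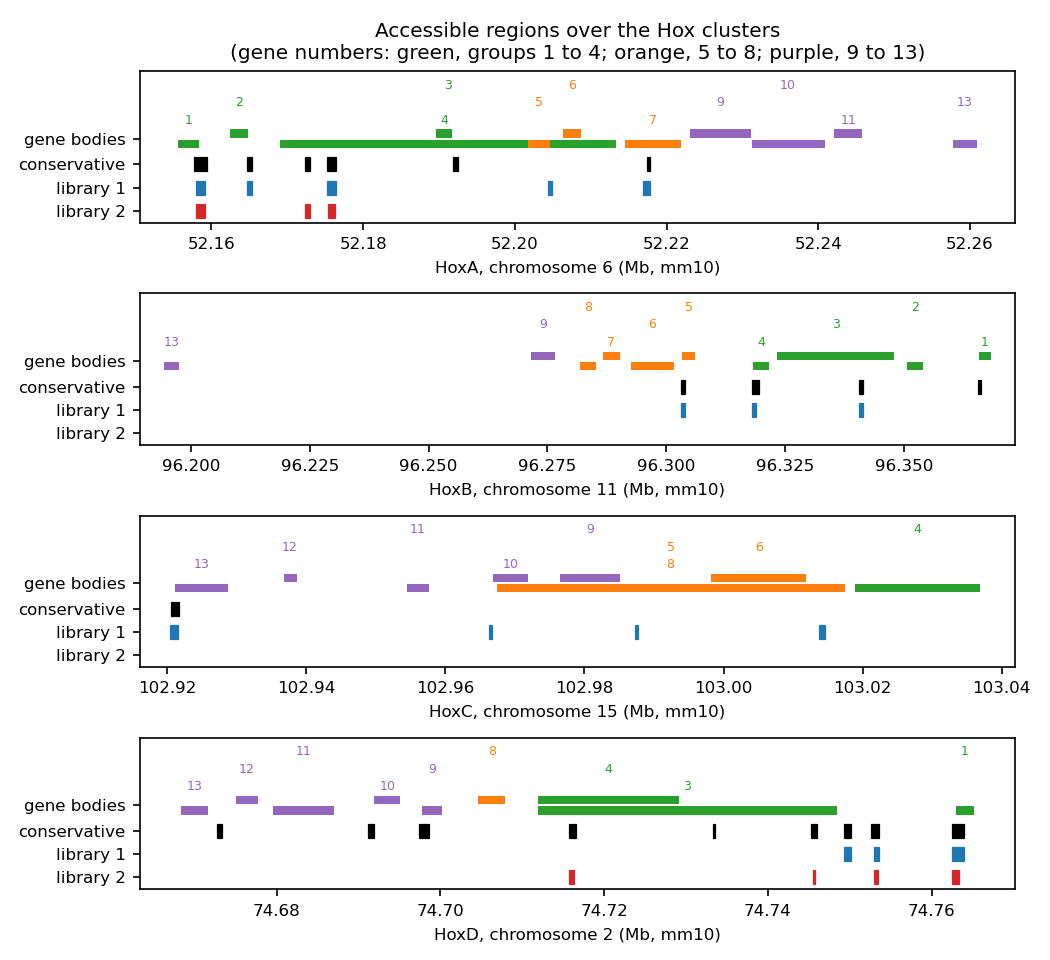
Position (Mb) of the conservative regions and of each library's regions along the 4 Hox clusters, drawn to scale with the Hox genes coloured by paralog group. Regions lie mainly at the anterior genes of HoxA, HoxB and HoxD, and within the HoxC genes the conservative list has a region only at Hoxc13.

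In distal regions 19 of the 30 motifs were more frequent at summits than in flanks, among them that of CTCF, which organises chromatin loops, motifs of widely expressed factors and several motifs bound by neural transcription factors. Among distal regions the CTCF consensus matched 5.27% of summit windows against 0.230% of flanks (22.9-fold). The E-box CAGCTG, bound by Ascl1, matched 25.1% against 9.53% (2.63-fold), and the E-box CAGATGG, bound by neurogenin-type factors, 9.85% against 4.50% (2.19-fold). The motif of ZIC proteins matched 4.35% against 1.71% (2.54-fold), the octamer of POU proteins 3.6% against 1.43% (2.52-fold) and the SOX consensus CCATTGTT 1.83% against 0.814% (2.25-fold). The RFX site GTTGCYA was 2.65-fold and the HOX-PBX consensus 1.73-fold enriched. These 8 motifs were called higher in the distal regions of each library as well. The EBF consensus, 2.21-fold, was called in library 1 and not in library 2. Motifs of widely expressed factors were enriched there as well, with SP and KLF sites at 3.71-fold, ETS at 2.65-fold and NFY at 1.58-fold. TFAP2 sites were at 2.18-fold. The E-box CATATGK of the Atoh and NeuroD type was lower at distal summits (0.782), and homeodomain (0.945) and ONECUT (0.916) sites were not called.

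The size of the distal ratios depended on the control. Against dinucleotide-shuffled windows the distal ratio was 29.5 for CTCF, 5.15 for the POU octamer, 3.87 for HOX-PBX, 2.47 for SOX, 2.08 for CAGATGG, 1.85 for RFX, 1.57 for CAGCTG and 1.44 for ZIC, and all were called higher. TFAP2 was not called against this control (1.02), NFY was lower (0.899), and homeodomain sites (3.64) and CATATGK (1.15) were higher.

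Promoter summits shared many of these motifs at other frequencies. There the ETS consensus matched 6.42% against 0.423% of flanks (15.2-fold), SP and KLF sites 44.2% against 10.1% and NFY sites 21.8% against 4.65%, and CTCF was enriched 5.56-fold. The HOX-PBX consensus (0.377) and CAGATGG (0.799) were lower at promoter summits than in flanks, opposite to their direction in distal regions. Flanks can lie inside the same region, and promoter regions were wider than distal ones (median 1260 against 852 bp). The flank controls of promoter and distal regions may therefore differ in kind. Against dinucleotide-shuffled windows the HOX-PBX consensus was higher at promoter summits (2.03, adjusted p 0.000423) and CAGATGG was not called (1.05). The HOX-PBX consensus was 8.55 times, the SOX consensus 4.37 times and CAGATGG 3.83 times as frequent at distal as at promoter summits. Over all regions 16 of the 30 motifs were higher at summits than in flanks, 6 were lower and 8 were not called. GATA sites had a ratio of 0.456, RUNX sites 0.625, HNF4 sites 0.512, the E-box CATATGK 0.62, homeodomain sites 0.688 and TEAD sites 0.868. Over all regions, with dinucleotide-shuffled windows in place of flanks, homeodomain (3.23), RUNX (1.5) and TEAD (1.18) sites were higher and TFAP2 sites (0.906) lower, each opposite to its direction against flanks. HNF4 sites (0.903) and CATATGK (1.05) were not called against that control, so of the 6 motifs lower against flanks only GATA was lower against both (0.783).

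The 10 strongest regions by signal had no gene of the tested lists as the nearest. The strongest was intergenic at chromosome X, 143482934 to 143483180 (signal 53.8), 35531 bp from the TSS of Pak3, followed by chromosome 2, 69355470 to 69355735 (46.9), near Abcb11, and chromosome 2, 3964420 to 3964690 (43.1), near Frmd4a. The next lay on chromosomes 10 (35.9), 5 (32.4), 12 (28.3), 8 (25.4), X (24.8), 9 (24.1, in an exon of Lars2) and 4 (23.4). Of these 10 regions, 5 match mitochondrial DNA, and the region on chromosome 8, without such a match, has 7 near-identical copies elsewhere, so the placement of the reads of these 6 is uncertain.

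Few strong regions were confined to a single library. The strongest library 1 regions without overlap in the pseudoreplicated list of library 2 had signals of 7.18 to 6.84. They lay nearest to Nrxn3 (13408 bp from its TSS), Hspbap1 (17309 bp), Sec61g (92243 bp), Nrp1 (132477 bp) and Grid2 (213969 bp). Grid2 is a glutamate receptor gene. The regions nearest to Nrp1 and Grid2 lay beyond the reach used to assign distal regions to genes. For library 2 the strongest such regions included those at the promoters of Litaf (7.34) and Cfap77 (5.47). The others lay nearest to Vgll2 (5.47, 111167 bp from its TSS), C030005K15Rik (5.47, 280470 bp) and Stmn2 (5.4, 263993 bp). All of these others lay beyond that reach too.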

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

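The tests of copies, of list length, of regulators against the hindbrain lists and of open promoters were planned before their results were seen. The test of mitochondrial matches among the strongest regions, the test of other cell types, and the test of regulators against the progenitor and neuronal lists were chosen only after the result was seen.

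The lists ranked by IDR, on which no comparison rests, hold signal that the thresholded lists lack. In library 1, 301 summits with the score of 540 or more that all thresholded summits have were in the ranked list and not in the thresholded list, out of 65649 that pass. In library 2 there were 265 of 47713. Of these, 113 and 93 lay on unplaced sequences or the mitochondrial genome, and 188 and 172 lay on chromosomes, in 75 and 72 regions. The widest was at chromosome 1, 24611586 to 24616156 (4571 bp) in library 1 and 24611587 to 24616163 (4577 bp) in library 2, an almost identical interval. It matches mitochondrial DNA, and it is the only 1 of the 75 and of the 72 regions that does. The deposited provenance notes give a further input to the thresholded lists only by an accession, and whether it removed these summits was not tested.

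The strongest regions were weighed first. Of the 10 strongest conservative regions, 5 match mitochondrial DNA over 129 to 365 bp at 95% to 100% identity, against 13 of all 25328 regions (Fisher's exact p 3.7e-15 against the others). Reads of mitochondrial DNA, which is free of nucleosomes, placed on nuclear copies of it are a candidate explanation for the regions with such a match, and for no others. The limit of 5 that the test used was set after the matches had been seen. Of the 50 strongest regions 6 match, so the rest are not covered by it. Near-identical copies elsewhere in the nuclear genome were found for 17 of the 50 strongest regions and for 2 of 100 others (Fisher's exact p 9.1e-08). That is more than in other regions but below the 25 that copies as the main cause were predicted to give, and the rest have none, so the tables do not decide how much of the high signal copies account for. No biological explanation was tested, since the design names no groups.

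The difference between the libraries was weighed next. Library 2 had a promoter share 9.18 percentage points above that of library 1. When library 1 was reduced to its 16912 strongest regions the gap was 1.957 points, so a longer list that reaches weaker, distal regions could account for most of it. Why library 1 gave the longer list is open, since no read depth is known. More cells of other types in library 1 would raise distal regions around their genes above those around neural genes. The ratio of library 1 to library 2 was 1.471 around genes of other cell types (50 against 34 regions) and 1.469 around neural genes (213 against 145, Fisher's exact p 1.0). Both lay below the ratio over all genes, 1.68 (6872 against 4084). With counts this small an admixture cannot be told apart from none.

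The excess of distal regions around hindbrain and neural genes was weighed last. If transcription factor loci of any tissue held more distal regions, regulators of other tissues would share the excess. The hindbrain genes had a mean excess over all genes of the same territory bin of 1.23 ± 1.62 (SD, n = 70 genes) and the regulators 0.0922 ± 0.844 (n = 62 genes), a difference of 1.136 regions per gene with a permutation p of 0.0001, the smallest the permutations can give. The progenitor and neuronal genes had a mean excess of 1.75 ± 1.72 (n = 47 genes), a difference of 1.659 from the regulators with the same smallest permutation p of 0.0001. The regulators were picked from the fixed lists after the data had been seen. They came from the forebrain, mesenchyme, muscle, gut and pancreas, endothelial, surface epithelium and hepatocyte lists. All genes of the forebrain list are among them, so they are not a non-neural baseline. No regulators were taken from the midbrain, neural crest, erythroid or macrophage lists. If genes with open promoters had more distal regions in general, the lists would fall to the level of random lists matched on open promoters, but 5 of the 5 lists stayed above. Ventral hindbrain genes had a smaller share of open promoters than other genes (39.1% against 58.5%). Matching lowered their random mean from 0.513 to 0.455, so that list cannot weigh on this explanation. These values argue against both explanations as the whole cause, the second only for the lists other than ventral hindbrain. That the regions are enhancers active in the hindbrain is a hypothesis that these lists do not test, since no other tissue and no expression were measured.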

How the results depend on the processing

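Counting every summit and reducing library 1 to the length of library 2 were chosen after seeing the data, and the other alternatives were planned. The cause of a change was not tested unless the alternative's construction, a longer or shorter list, gives it.

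The number of regions depends on the list by construction. It was 51321 in library 1 and 42245 in library 2 with the pseudoreplicated lists, 11074 and 8456 with the 50% of highest signal, and 65348 and 47448 when every summit was counted. The share of library 1 regions shared with library 2 was 69.0% with a reciprocal overlap of 50%, 69.9% with summits within 100 bp, 87.1% with equal numbers of the strongest regions and 67.2% with the pseudoreplicated lists. For library 2 the shares were 90.3%, 92.4%, 87.2% and 84.7%. The rank correlation was 0.913 with the reciprocal overlap, 0.786 over distal and 0.920 over promoter regions.

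The promoter share was 30.5% in the replicated list, 74.5% in the 50% of highest signal and 65.8% in the reduced library 1, and with a replicate left out it ranged from 58.6% to 67.8%. The optimal list, the windows of 500 and 2500 bp and all summits gave 50.2% to 59.9%.

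The lists called with more open promoters numbered 1 in the 50% of highest signal and 1 in the reduced library 1, against 3, and 3 to 4 with a replicate left out. Those called with fewer numbered 4 in the replicated list and 13 in the 50% of highest signal, against 8, and 7 to 9 with a replicate left out. By list, 137 of the results under an alternative stayed on the same side of the threshold, 9 ended a call and 11 made one. Some of the 137 changed direction without a call, as Hox groups 1 to 4 and midbrain genes did with either replicate left out. The remaining results changed direction and were called in the conservative list or under the alternative. Hox groups 1 to 4 were at -35.0 points against other genes in the reduced library 1. Hox groups 5 to 8 were 7.20 points above in the replicated list, and dorsal hindbrain genes were at -31.6 points in the 50% of highest signal.

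The lists called with more distal regions numbered 8 in the replicated list, 2 in the 50% of highest signal and 3 in the reduced library 1, against 5, and 4 with either replicate left out. By list, 187 results kept their side, 8 ended a call (5 for ventral hindbrain genes, and 1 each for the dorsal hindbrain and neuronal lists in the 50% of highest signal and the isthmus and rhombomere list in the reduced library 1), and 5 made one. The Hox difference kept its direction and its call under every alternative run, at 0.0708 and 0.201 regions per kb in the optimal and replicated lists, 0.0499 to 0.0657 with a replicate left out, and 10.4 percentage points in base pairs covered.

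The motifs called lower numbered 2 among distal regions, 12 among promoter regions and 2 against shuffled windows, against 6. The number called higher stayed within 1.5 times of 16 under every alternative run. By motif, 174 results kept their side, 12 ended a call and 16 made one. Reversed against flanks were SOX_core at 0.691 in promoter regions and 0.953 in 400 bp windows, HOX_PBX at 0.377 and the E-box CAGATGG at 0.799 in promoter regions (against shuffled windows these promoter ratios were 1.51, 2.03 and 1.05, the last not called), and against shuffled windows homeodomain at 3.23, TEAD at 1.18, TFAP2 at 0.906 and RUNX at 1.5. Without replicate 1 and without replicate 2, SOX_core and HOX_PBX over all regions were no longer called. Of the counts of distal regions of named genes, 439 moved by less than the spread between the libraries and 297 by more.

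The unknown read depth limits every list: a region absent from a list was not called at that depth, and is not shown to be closed.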

Other observations

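All tests in this part were chosen only after the data had been seen, over 350 gene families defined by the stem of the gene symbol with 8 to 200 members, and they are hypotheses for other data.

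Genes of the Pou family, POU-domain transcription factors of which several direct neuronal fate, had a mean of 2.12 distal regions per gene against 0.641 in matched random lists (3.32-fold, 16 genes, adjusted p 0.0233), and were called in library 1 (1.81) and library 2 (1.31) too. Histone genes, which lie in dense clusters and are transcribed in dividing cells, had 0.194 against 0.0382 (67 genes, adjusted p 0.0233), with 94.0% of their promoters open. They were called in library 1 (adjusted p 0.035) and not in library 2 (adjusted p 0.122). The Btbd family was the only family called lower, with 0.0698 against 0.649 (43 genes, adjusted p 0.0233) and 25.6% of promoters open, and it was called in both libraries. Near-identical copies of its members elsewhere in the genome were not sought. Whether uncertain placement of reads lowered its counts was therefore not tested. The Wnt (1.21 against 0.353, adjusted p 0.0525), Sox (1.89 against 0.702, adjusted p 0.08) and Pax (2.56 against 0.728, adjusted p 0.08) families had higher means that did not pass. Members of the Pou, Wnt, Sox and Pax families are also in the fixed lists, so these values are not independent of theirs.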
